A study of Homo sapiens with 20 samples.

How the data were processed

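The study exposed PC9-C2, an isogenic derivative of the EGFR-mutant human lung cancer line PC9, to 0.1% DMSO or to 2 µM osimertinib, an inhibitor of mutant EGFR. Cells were frozen at 5 DMSO times (0.5, 2, 8, 24 and 48 h) and 9 osimertinib times (0.5, 2, 8, 24, 48, 72 and 96 h, 6 d and 9 d), which makes 14 conditions. The thawed samples were stained with TotalSeq-A hashtag antibodies, which carry a DNA tag that marks the sample of origin of each cell. The titles of the 8 single-cell lanes call each of them a batch of all samples. Their treatment field instead gives DMSO for lanes 1 to 4 and osimertinib for lanes 5 to 8, and their genotype field gives parental for lanes 1 to 4, acute for lanes 5 and 6 and drug-tolerant persister for lanes 7 and 8. The 8 lanes were kept in 1 group after their titles. Of the 14 hashtags, 13 were called in every lane, lane 8 included. If each hashtag marked 1 condition, a lane with the 5 DMSO or the 9 osimertinib conditions alone could not hold 13 hashtags, and under that condition the titles, not these fields, describe the content of the lanes. Hashtags 4 and 11 differed between lanes, so spread between lanes is not shown to be technical alone. The 12 samples of barcode DNA sequencing, 3 replicates in each of 4 groups, were not analysed here.

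The deposited hashtag tables give for every cell the fraction of hashtag signal in each of 14 tags, the tag with the largest fraction, and the gap between the largest and the second largest fraction, per the file headers and the values. How the authors counted and filtered the tags is not given in the sources used here. The deposited expression matrix of lane 8 holds whole-number UMI counts per gene and cell, not normalized; Cell Ranger 2.1.1 and the build GRCh38 are named in the submitters' processing notes. Expression of lanes 1 to 7 was not used here.

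Hashtags appear in the tables only as 15-base sequences. No key from tag to condition was used here, so hashtags were numbered in alphabetical order of sequence and left unassigned. The numbers run from AAATCTCTCAGGCTC (1), AAGTATCGTTTCGCA (2), AGTAAGTTCAGCGTA (3), ATTGACCCGCGTTAG (4), CAGTAGTCACGGTCA (5), CTCCTCTGCAATTAC (6) and CTGTATGTCCGATTG (7) to GGTTGCCAGATGTCA (8), GTCAACTCTTTAGCG (9), TAACGACCAGCCATA (10), TAAGATTCAGAGCGA (11), TGATGGCCTATTGGG (12), TGTCTTTCCTGCCAG (13) and TTCCGCCTCTCTTTG (14). No comparison of osimertinib with DMSO, no differential expression test and no clone analysis was made. Each hashtag was treated as 1 sample, which is not shown for hashtag 11 in lanes 5 to 8, so values are given per hashtag, or as range and median, without p-values.

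A cell counted as singly called when the gap between its top fractions was at least 0.5. This limit was set after the data had been seen, as were the 4-fold limit, the pseudocount of 5 CPM and the clustering settings given below. A gap of at least 0.8 and no limit were run as alternatives. It is meant to remove pairs of cells with different hashtags, and how many it removed was not measured. Pairs with the same hashtag remain, and at the shares found in lane 8 they would make up 11.1% of randomly formed pairs. No other doublet caller was run. No filter on UMIs or mitochondrial share was applied in the main values. Cells with at least 1000 UMIs and under 20% mitochondrial UMIs were an alternative.

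UMI counts of the singly called cells were summed per hashtag and per cluster and scaled by the total to give CPM, the share of UMIs times 1e6. Intervals are exact 95% Poisson intervals for sums and exact conditional binomial intervals for ratios of sums. For shares they are exact 95% binomial (Clopper-Pearson) intervals. For list levels they are the central 95% of levels from 200 Poisson draws of the sums. All of them cover counting error only. Where a count of cells was 0, the share it allows is given as 3 cells of the total, a lower limit than that of the exact interval. The range of a gene is its highest over its lowest CPM, with the lowest taken as no less than 3 counts. Genes of at least 20 CPM in the pooled cells were counted as wide-ranging when this ratio was at least 4. The level of a gene list is the mean over members of log2(CPM + 5), relative to the median hashtag. Sums with counting error only were simulated from the pooled lane 8 profile over 5501 genes. All 100 genes changed 8-fold in 1 hashtag passed the limit of 4. None of 100 genes changed 2-fold did, and none of 5301 unchanged genes did. Spread between cells, pairs of cells and free RNA were not simulated, so passes from these sources were not measured.

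Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). Clusters were numbered by size and given no cell type name. Cell cycle calls used the S and G2M lists on cells thinned to 3000 UMIs, which left out 1773 shallower cells. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0. Symbols and Ensembl identifiers are those of the matrix, where CCN1 and CCN2 appear as CYR61 and CTGF. Gene positions come from the RefSeq annotation of GRCh38.

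The grouping of the lanes, the gene lists, the rule for named genes and the fallback to values per hashtag were fixed before the data were examined. With no condition assigned, the rule names up to 4 members per list with the widest range across clusters, the 5 leading genes of each cluster, and a fixed set of EGFR, MAPK, YAP, cell cycle and apoptosis genes whatever their values; genes named outside it are marked where they appear. Alternatives changed the cells, the scaling, the depth, the lanes and the clustering. The count for 1 gene list is not reported here.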

Results

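Single-cell RNA sequencing with hashtag antibodies was carried out on a pool of PC9-C2 lung cancer cells exposed to DMSO or osimertinib for different times. The title of the series names focal adhesion kinase and YAP signalling in drug-tolerant cells as its subject. The 8 lanes held 153840 barcodes, between 14426 and 21371 per lane. Of 153818 cells in the hashtag tables, 121367 (78.9%) were singly called, and the share per lane was 79.2% ± 3.73 (SD, n = 8 lanes). Expression was analysed in lane 8, where 12350 of 14426 cells were singly called. Their median was 7975 UMIs and 2572 genes per cell, and the 13 hashtags called there summed to between 2180552 and 19234270 UMIs. Hashtags were not assigned to treatments, so the values below describe hashtags of unknown condition, each with 1 expression sum. Hashtag 11, which gave the highest values of DUSP6, EGR1, CXCL1 and ASNS, is not shown to be 1 sample.

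Hashtag 2 (AAGTATCGTTTCGCA) marked the largest share of singly called cells, 20.9% ± 0.501 (SD, n = 8 lanes), followed by hashtag 8 (GGTTGCCAGATGTCA) at 15.96% ± 0.743. Hashtag 6 marked 2.81% ± 0.211 and hashtag 12 marked 3.24% ± 0.381. The other hashtags apart from 4 and 11 had mean shares between 3.60% and 7.88%. Hashtag 4 (ATTGACCCGCGTTAG) marked 6.07%, 5.92%, 5.93% and 5.73% of cells in lanes 1 to 4. It was called in 0 of 17206, 0 of 16071, 0 of 14508 and 0 of 12350 cells in lanes 5 to 8, which allows shares of up to 0.0174%, 0.0187%, 0.0207% and 0.0243%. Hashtag 11 (TAAGATTCAGAGCGA) marked 6.34%, 6.06%, 4.43% and 6.10% in lanes 1 to 4 and 10.4%, 10.0%, 10.3% and 9.85% in lanes 5 to 8. The exact 95% binomial interval was 5.97% to 6.73% for hashtag 11 in lane 1 and 9.33% to 10.4% in lane 8. In lane 8, 13 of the 14 hashtags were called.

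**Figure D1:**
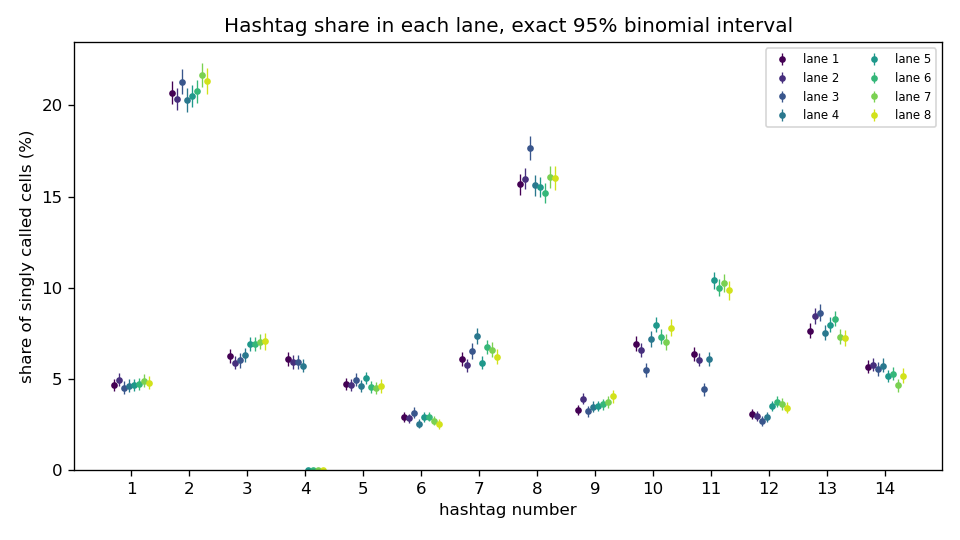
Share of singly called cells (%) carrying each of the 14 hashtags, 1 point per lane with its exact 95% binomial interval. Hashtag 4 lies near 6% in lanes 1 to 4 and at 0 in lanes 5 to 8, while hashtag 11 lies between 4.43% and 6.34% in lanes 1 to 4 and between 9.85% and 10.4% in lanes 5 to 8.

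Across the 13 hashtags of lane 8, 642 of 5501 genes with at least 20 CPM in the pooled cells ranged at least 4-fold. The counts given for each list below cover its members with at least 20 CPM in the pooled cells, and some members named with their values lie under that level. TOP2A (ENSG00000131747, chromosome 17, 40388525 to 40417896), the topoisomerase that untangles DNA in dividing cells, ranged from 39.8 CPM in hashtag 5 to 561 CPM in hashtag 14, with a median of 441. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126423), a marker of cycling cells, ranged from 26.5 CPM (95% Poisson interval 21.3 to 32.7) in hashtag 5 to 360 CPM (346 to 374) in hashtag 1. Of the G2M list, 48 of 54 members had at least 20 CPM and 40 of these ranged at least 4-fold, among them GTSE1 (3.91 to 57.5 CPM) and NUF2 (2.71 to 44.7 CPM). Of the S phase list, 26 of 32 such members did, among them CLSPN (7.53 to 124 CPM) and EXO1 (3.74 to 41.7 CPM), both used in DNA replication and repair. The share of thinned cells called S or G2M ranged from 4.07% in hashtag 5 to 98.3% in hashtag 7, with a median of 78.0%, and from 7.80% in hashtag 8 to 96.99% in hashtag 9 without thinning. Free RNA in the droplets enters such calls and was not removed. The calls rest on list scores relative to other genes, and a cell is left uncalled only where both scores are low. These shares therefore rank the hashtags and are not measured fractions of cells in S or G2M. The ranges changed with the limit on the hashtag gap, which also changes which cells are kept: the cells left out of lane 8 had a median of 14510.5 UMIs. The MKI67 ratio of highest to lowest was 13.6 at a gap of at least 0.5, 49.1 at a gap of at least 0.8 and 6.18 with no limit, and that of TOP2A was 14.1, 26.7 and 5.89.

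EGFR (ENSG00000146648, chromosome 7, 55019017 to 55211628) ranged 2.77-fold, from 178 CPM in hashtag 2 to 493 CPM in hashtag 12. Of the genes induced by MAPK signalling below the receptor, 6 of 6 members ranged at least 4-fold. CCND1 (ENSG00000110092, chromosome 11, 69641156 to 69654474), the cyclin that drives entry into the cell cycle, ranged from 95.8 CPM (91.5 to 100.3) in hashtag 2 to 611 CPM (592 to 630) in hashtag 9. DUSP6 (ENSG00000139318, chromosome 12, 89347235 to 89352501), a phosphatase that acts on ERK, was at 0.602 CPM (0.0729 to 2.18) in hashtag 5 and 15.3 CPM (13.0 to 17.9) in hashtag 11. SPRY4, another feedback inhibitor, did not exceed 4.66 CPM. FOSL1 ranged from 5.93 CPM in hashtag 2 to 97.02 CPM in hashtag 10, AREG from 3.31 to 48.4 CPM and ETV5 from 2.71 to 36.8 CPM. The immediate early gene EGR1 was at 0.411 CPM (0.0848 to 1.20) in hashtag 14 and 43.0 CPM (39.1 to 47.2) in hashtag 11. In hashtag 14 CCND1 stood at 267 CPM and DUSP6 at 0.686 CPM beside TOP2A at 561 CPM, and in hashtag 3 CCND1 stood at 171 CPM beside TOP2A at 441 CPM. Among receptor tyrosine kinases, 2 of 4 members ranged at least 4-fold, ERBB2 (9.49 to 41.8 CPM) and ERBB3 (24.2 to 100.2 CPM), both named after their values were seen. EPHA2 ranged from 2.099 to 23.1 CPM. The EGR1 value of hashtag 14 rests on 3 counts, and the ratio of highest to lowest was 105 (exact 95% interval 35.6 to 509). It was 29.4 with no limit on the hashtag gap. With hashtags thinned to the same total it was 31.3, a lower bound because the lowest is taken as no less than 3 counts. For DUSP6 the lowest and highest hashtags after such thinning were 14 and 9.

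**Figure D2:**
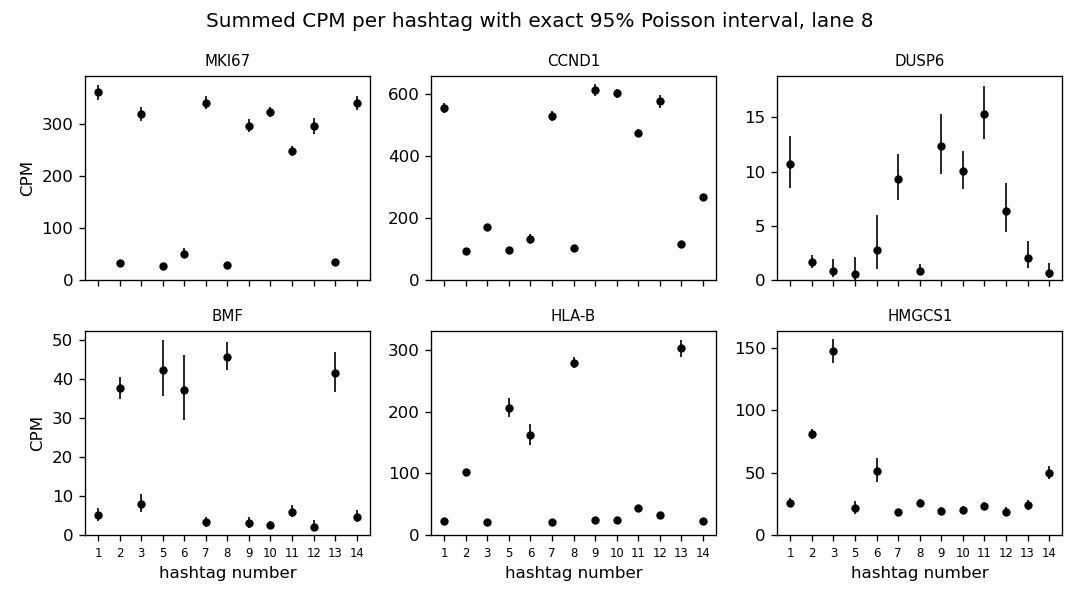
Summed CPM of MKI67, CCND1, DUSP6, BMF, HLA-B and HMGCS1 for each of the 13 hashtags of lane 8, with exact 95% Poisson intervals; every axis starts at 0. Hashtag 14 has MKI67 at 340 CPM with DUSP6 at 0.686 CPM, and HMGCS1 is highest in hashtag 3 at 148 CPM.

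YAP1 (ENSG00000137693, chromosome 11, 102110447 to 102233424), which encodes a transcriptional coactivator, ranged from 37.4 to 54.2 CPM, its DNA-binding partner TEAD1 from 49.96 to 68.0 CPM, and PTK2 (ENSG00000169398, chromosome 8, 140657900 to 141002079), which encodes focal adhesion kinase, from 44.7 to 82.8 CPM. Of the YAP and TEAD target list, 5 of 14 members ranged at least 4-fold. They were IGFBP3, CCDC80 and, named after their values were seen, F3 (24.0 to 162 CPM), CRIM1 (37.3 to 173 CPM) and TGFB2 (11.5 to 49.4 CPM). ANKRD1 was at 0.411 CPM (0.0848 to 1.20) in hashtag 14 and 35.3 CPM (31.0 to 40.1) in hashtag 9. Its low value rests on 3 counts, and the ratio was 85.9 (29.0 to 419), and 36.3 with no limit on the hashtag gap. After thinning it was 25.3, a lower bound set by the floor of 3 counts. IGFBP3 ranged from 20.7 CPM in hashtag 7 to 937 CPM in hashtag 5, and CCDC80 from 19.7 to 205 CPM between the same hashtags. CCN1 ranged from 13.2 CPM in hashtag 14 to 51.4 CPM in hashtag 6, AMOTL2 from 33.5 to 127 CPM, and CCN2 did not exceed 8.73 CPM. Of the focal adhesion list, 4 of 21 members ranged at least 4-fold. The integrin gene ITGA6 ranged from 13.3 CPM in hashtag 5 to 113 CPM in hashtag 12, and ITGB6 from 9.12 CPM in hashtag 7 to 81.9 CPM in hashtag 5. The other 2, named after their values were seen, were ITGA2 (26.2 to 211 CPM) and THBS1 (17.5 to 124 CPM). AXL was at most 0.579 CPM. In the list of genes tied to drug tolerance, which also holds IGFBP3, 2 of 8 members ranged at least 4-fold, IGFBP3 and AURKA (21.1 to 188 CPM). AURKA also led cluster 9, described below, together with the cell division gene TOP2A. ALDH1A1 reached 15.5 CPM in hashtag 8.

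BMF (ENSG00000104081, chromosome 15, 40087890 to 40108879), which encodes a BH3-only protein that promotes cell death, ranged from 2.07 CPM (1.03 to 3.70) in hashtag 12 to 45.8 CPM (42.3 to 49.5) in hashtag 8. Its ratio of highest to lowest was 22.1, and 12.7 with no limit on the hashtag gap. BCL2L11, which encodes BIM, ranged from 16.9 CPM in hashtag 12 to 43.8 CPM in hashtag 2. Of the BCL2 family members with 20 CPM in the pooled cells, 0 of 4 pro-apoptotic and 0 of 2 anti-apoptotic ones ranged 4-fold or more. BMF and BBC3 (1.05 to 10.5 CPM), under that level, did range more than 4-fold. BCL2L1 came close to the limit at 3.98-fold (24.1 to 96.1 CPM), and MCL1 ranged from 30.3 to 94.5 CPM. In the interferon list HLA-B ranged from 20.4 CPM in hashtag 7 to 303 CPM in hashtag 13, and IFIT2 from 0.798 to 39.0 CPM. Of the interferon list, 6 of 8 members ranged at least 4-fold. Of p53 targets 0 of 1 did, since only 1 of 11 members had 20 CPM in the pooled cells. Members under that level did range: BTG2 from 1.95 CPM in hashtag 9 to 45.1 CPM in hashtag 8, and TP53INP1 from 0.617 to 19.7 CPM. CDKN1A, also under it, ranged from 7.98 CPM in hashtag 7 to 34.4 CPM in hashtag 6. Of NF-kB targets 1 of 3 ranged at least 4-fold, TNFAIP2 (167 to 771 CPM), named after its values were seen. CXCL1 ranged from 0.549 CPM in hashtag 14 to 22.4 CPM in hashtag 11. Immediate early genes that also respond to cell handling were wide-ranging in 6 of 8 members, with FOS between 2.07 CPM in hashtag 12 and 202 CPM in hashtag 6.

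Of cholesterol and fatty acid synthesis genes, 8 of 14 ranged at least 4-fold. HMGCS1, an early enzyme of cholesterol synthesis, ranged from 18.1 CPM in hashtag 7 to 148 CPM in hashtag 3, and SCD, which desaturates fatty acids, from 51.8 CPM in hashtag 7 to 411 CPM in hashtag 2. Of glycolysis genes 0 of 13 did, and of fatty acid oxidation genes 0 of 6 did; ENO1 ranged from 343 to 1269 CPM and HADHB from 32.5 to 114 CPM. Of integrated stress response genes 3 of 6 did, DDIT4 (10.7 to 65.5 CPM), PSAT1 (10.8 to 65.3 CPM) and, named after its values were seen, PHGDH (14.1 to 98.9 CPM). ASNS was highest in hashtag 11 at 26.8 CPM. Of mitochondrial transcripts 1 of 13 did, MT-ATP8 (151 to 707 CPM). The level of this list was highest in hashtag 3, where MT-ND1 stood at 10215 CPM against a median of 6162. In hashtag 3, 47.8% of cells (44.4% to 51.1%) had at least 20% mitochondrial UMIs, against 6.47% (4.00% to 9.82%) in hashtag 6. The list level of hashtag 3 was 0.779 log2 units above the median hashtag. It was 0.093 in cells with at least 1000 UMIs and under 20% mitochondrial UMIs. That filter leaves out cells by the same transcripts, so a fall was set in advance and tests no cause. The epithelial list had 1 of 12 members at 4-fold or more, ELF3, from 60.9 to 628 CPM. The squamous list had 1 of 1, KRT15, from 17.7 to 87.9 CPM. The alveolar list had 0 members at 20 CPM, and HOPX reached 3.70 CPM.

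**Figure D3:**
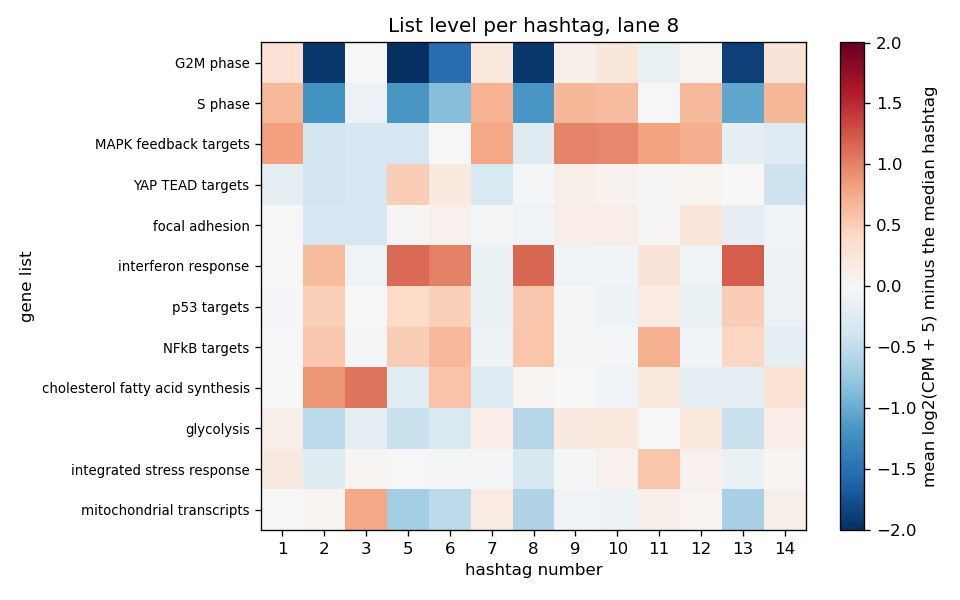
Level of 12 gene lists in each of the 13 hashtags of lane 8, as the mean of log2(CPM + 5) over members minus the median hashtag. The G2M list spans 2.29 log2 units, the S phase list 1.89, the MAPK list 1.36 and the YAP and TEAD target list 0.91.

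The 12350 cells formed 10 clusters. Clusters led by histone genes such as HIST1H1D (cluster 2, 2023 cells), by DTL and PTTG1 (cluster 5, 1277 cells) and by AURKA and TOP2A (cluster 9, 558 cells) were among them. Cluster 1 (2755 cells) was led by IGFBP5 and CFD, cluster 3 (1752 cells) by TM7SF2 and ALDOC, cluster 6 (949 cells) by EGR1 and ASNS, and cluster 7 (744 cells) by PDZK1IP1 and the acute phase genes SAA1 and SAA2. Cluster 4 (1387 cells) had a median of 279 genes and 79.0% mitochondrial UMIs, and cluster 8 (666 cells) a median of 38.8% mitochondrial UMIs. Cluster 10 (239 cells) combined a median of 17528 UMIs with the lowest median hashtag gap, 0.656. Cluster 3 held 60.0% of hashtag 2 cells (58.1% to 61.8%) and at most 5.50% of any other hashtag. Cluster 1 held 79.6% of hashtag 5, 72.1% of hashtag 13, 71.9% of hashtag 8, 63.1% of hashtag 6 and 1.63% of hashtag 2. It held 0 cells of the other hashtags, of which hashtag 11 had 0 of 1217, which allows a share of up to 0.247%. Cluster 6 held 44.5% of hashtag 11 (41.6% to 47.3%) and 24.2% of hashtag 3. Of cluster 3 cells, 90.1% came from hashtag 2.

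**Figure D4:**
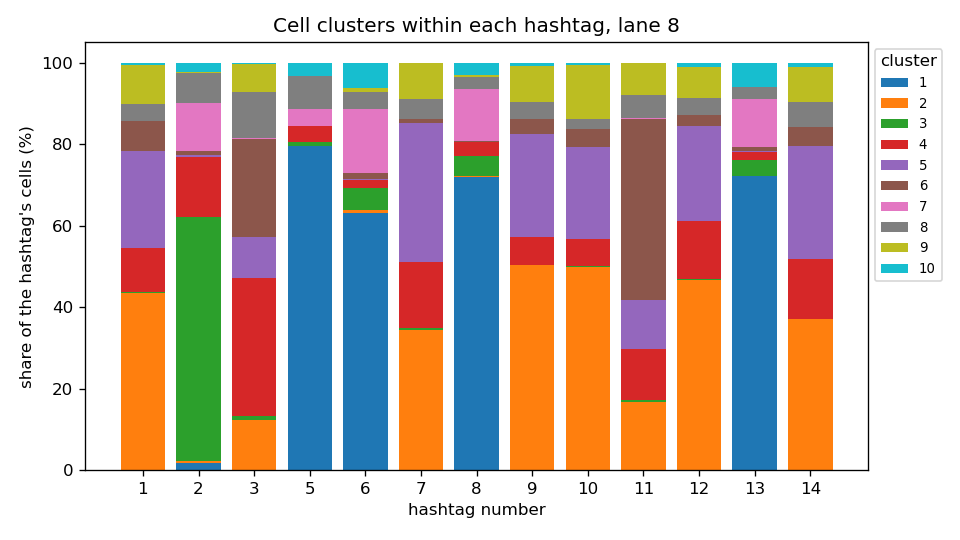
Share (%) of each hashtag's singly called cells of lane 8 that fell in each of the 10 clusters; each bar sums to 100. Cluster 3 makes up 60.0% of hashtag 2, and cluster 6 makes up 44.5% of hashtag 11.

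Of the fibroblast markers COL1A1 reached 3.08 CPM, of the immune markers CD68 reached 22.3 CPM and CD14 0.602 CPM, and of the endothelial markers CDH5 reached 8.73 CPM in hashtag 5 and PECAM1 1.51 CPM. None of the members of these lists had 20 CPM in the pooled cells.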

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

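The tests of explanations in this part were all chosen after the results had been seen.

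Hashtag 8 marked 17.7% of singly called cells in lane 3, apart from the other 7 lanes, of which the next highest had 16.1%. It was the 1 set out of 18 sets of 8 lanes tested in which a lane stood apart, and chance alone gives about 1 in 20 groups. The flag also depended on the limit on the hashtag gap. Among all barcodes hashtag 8 marked 15.4% in lane 3, 15.5% in lane 7 and 15.6% in lane 8, so lane 3 was not the highest.

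Hashtag 4 was called in lanes 1 to 4, whose treatment field gives DMSO, and in none of lanes 5 to 8, whose field gives osimertinib. Whatever the gap, hashtag 4 was the largest fraction in 0 cells of lanes 5 to 8, the unclear cells included. Loss of its signal that left its cells without a clear call was set to bring such cells to 25.8% or more. This bound adds the lowest of lanes 1 to 4 (20.03%, of all cells) to the lowest hashtag 4 share there (of singly called cells). It is too high, since the 849 singly called hashtag 4 cells of lane 4 are a smaller share of its 18543 cells. Lanes 5 to 8 had 19.0%, 23.2%, 18.1% and 14.4%, with a median of 18.6%. Of these 4, 3 lay below 25.8% by more than the larger SD of both sets of lanes, 3.64. The same 3 also lay below 20.03% itself. This argues against such loss only if the lanes otherwise had like shares of unclear cells, and lanes 7 and 8 also held fewer barcodes. Loss with the cells called under other hashtags was not tested. A pool that differed only by the lack of this sample would leave hashtag 11 unchanged, and hashtag 11 made 4.94 to 7.24 cells per 100 cells of the other 12 hashtags in lanes 1 to 4 and 10.9 to 11.6 in lanes 5 to 8, which argues against it. A candidate explanation is that the hashtag 4 sample carried hashtag 11 in lanes 5 to 8: hashtags 4 and 11 together made 14.2, 13.6, 11.6 and 13.4 in lanes 1 to 4, so the ranges meet through lane 3 alone, and this cannot be told apart from a pool with other amounts of several samples, since expression of lanes 1 to 4 was not used here, and no biological explanation was tested.

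Hashtag 11 cells of lane 8 were divided between cluster 6 and clusters 2, 5 and 9. Had the 448 cells in clusters 2, 5 and 9 been cells of the other hashtags in general, miscalled, 689 would be needed in clusters 1, 3 and 7, and 6 were found, which argues against it. Miscalls from particular hashtags at a gap under 0.8, as the whole cause, would bring the share of hashtag 11 in cluster 6 to 70.4% at a gap of at least 0.8, and it was 45.6% (41.5% to 49.7%) against 44.5% in all its singly called cells, which argues against them; miscalls with a larger gap stay open. Among cells called S or G2M, 23.3% (19.98% to 26.8%) of hashtag 11 lay in cluster 6, against 22.6% in hashtag 3 and 9.60% in hashtag 2. The other hashtags compared had between 0.158% (hashtag 7) and 3.04% (hashtag 1), and hashtags of under 100 such cells were not compared. Hashtag 11 exceeded all of these but hashtag 3 beyond counting error. The test took the highest other hashtag as its reference, and hashtag 3 itself had 24.2% of its cells in cluster 6. It therefore could not decide whether cell cycle phase is the whole cause, which stays open. Clusters 2, 5 and 9 had G2M list levels of 1.08, 1.15 and 2.38 log2 units relative to the median cluster. Cluster 6 had -0.626. Of the 541 hashtag 11 cells in cluster 6, 142 were called S or G2M. Hashtag 11 as a whole had 610 such cells among 1020 deep enough to be called, and 197 were too shallow. The division thus went with phase in part. A mixture of samples under hashtag 11 may also give such a division, and neither that nor a biological explanation was tested.

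The cholesterol and fatty acid synthesis list was highest in hashtag 3, which also had the largest share of cells with at least 20% mitochondrial UMIs. Damaged cells are unlikely to be the whole cause: without cells of high mitochondrial share or under 1000 UMIs the level of hashtag 3 was 1.12 (1.07 to 1.18) log2 units above the median hashtag, against 1.06 with them. RNA of hashtag 2 cells would leave hashtag 3 at or below hashtag 2, and hashtag 3 lay 0.18 (0.13 to 0.21) log2 units higher, with 13 of 18 members higher, which argues against it as the whole cause. Differences in staining, thawing or treatment between samples stay open, and no biological explanation was tested.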

How the results depend on the processing

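Alternatives on the hashtag gap, the 2 other scalings and the omission of single hashtags were chosen after seeing the data. Wide-ranging genes numbered 642 in the main analysis and 436 to 782 under 6 alternatives; 435 of the 436 genes found with no limit on the gap and 637 of the 782 found at a gap of at least 0.8 were among the 642. The number of clusters was 10, and 8 to 13 under other settings. Among all barcodes the mean shares of hashtags 1, 2, 7 and 8 moved by more than 1 SD, to 4.91%, 19.9%, 6.99% and 14.98%; the other 10 shares, and all shares without single lanes, moved by less. The median share of cells called S or G2M, 78.0%, was 83.9% without thinning and 68.9% to 85.9% without single hashtags. Of list ranges, 63 of 150 alternative values left the counting interval of the main value. Thinning hashtags to the same total moved the ratios of highest to lowest of DUSP6, SPRY4, EGR1, CDKN1A, CCN2, ANKRD1 and AXL by more than 1.5 times. Where the lowest sum held at most 3 counts after thinning, as for EGR1 and ANKRD1, the ratio is a lower bound set by that floor. The AXL ratio went from 3.71 to 0.333, which lies below 1 only because of the same floor. Median-of-ratios scaling moved the median gene of hashtags 5, 6, 8 and 13 by -0.16, -0.12, -0.12 and -0.11 (log2) relative to the median hashtag, and leaving mitochondrial genes out of the totals moved that of hashtag 3 by 0.12. No paired analysis was possible because the groups that share replicate numbers, those of barcode DNA, were not analysed here, and hashtags carry no replicate number. All planned comparisons of osimertinib with DMSO, with their tools, filters, controls and gene list tests, and the clone analysis were not run, since no hashtag was assigned to a condition. Depth limits genes under about 1 CPM, where the sums of hashtags with few cells hold only a few counts.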

Other observations

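The hashtags of lane 8 fell into separate clusters of values for several genes, given here for samples of unknown condition without an explanation. MKI67 stood at 360 CPM in hashtag 1, 32.2 in hashtag 2, 318 in hashtag 3, 26.5 in hashtag 5, 50.9 in hashtag 6, 340 in hashtag 7, 29.4 in hashtag 8, 296 in hashtag 9, 323 in hashtag 10, 247 in hashtag 11, 295 in hashtag 12, 35.4 in hashtag 13 and 340 in hashtag 14. In the same order BMF stood at 5.00, 37.7, 7.95, 42.5, 37.1, 3.19, 45.8, 3.01, 2.62, 5.88, 2.07, 41.7 and 4.66 CPM, with no value between 7.95 and 37.1. CCND1 stood at 554, 95.8, 171, 96.4, 133, 528, 102.9, 611, 601, 473, 575, 115 and 267 CPM. Hashtags 3 and 14, at 171 and 267 CPM, lay between the values of 133 and 473 CPM, while their MKI67 values lay among the highest. DUSP6 in these 2 hashtags was at 0.900 CPM (0.330 to 1.96) in hashtag 3 and 0.686 CPM (0.223 to 1.60) in hashtag 14.

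Cluster 7, led by PDZK1IP1, SAA1 and S100A8, was spread unevenly over hashtags. It held 11.8% of hashtag 2 cells (exact 95% binomial interval 10.6% to 13.1%), 4.39% of hashtag 5, 15.9% of hashtag 6, 12.8% of hashtag 8 and 11.6% of hashtag 13, 1 cell each of hashtags 3 and 11, and 0 cells of hashtags 1, 7, 9, 10, 12 and 14, which allows shares of up to 0.711% (hashtag 12, the fewest cells of these). Cluster 10, with a median of 17528 UMIs, held at most 6.15% of any hashtag. Its 239 cells were also unevenly spread. Hashtags 2, 5, 6, 8 and 13, those with more than 1 cell in cluster 7, gave 60, 19, 19, 60 and 53 of them. Any other hashtag gave at most 6.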
